A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

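PolyA RNA of the fission yeast Schizosaccharomyces pombe was compared on 4 arrays with 2 channels each. Per the labels, channel 1 held RNA of a strain taken 30 min after a shift to 36 °C, and channel 2 held RNA of the same strain growing at 25 °C in rich liquid medium (YES). Strain JV558 was the wild type and strain JV565 carried mmi1-ts3, a temperature-sensitive allele of mmi1, with 2 arrays each. Between 3 and 6 µg of polyA RNA was labelled. The replicate numbers follow the order of the records, and the labels name no pairing. One array of each strain has a code in its title and the other has none; these are called the coded and the uncoded array set, and they are the only batch the labels give. In both strains replicate 1 is the uncoded and replicate 2 the coded array, so a block on the array set is also a block on these numbers.

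The deposited values are log2 ratios of the channels of each array, as read here from the values, since the log base is not given in the sources used here. Base 10 was excluded because the highest value, 7.81, lies above 4.82, the whole range of a 16-bit scanner as a base-10 logarithm. A natural log is not excluded by the values, and every log2 value below would then lie further from 0 and every fold further from 1. The authors' background correction, normalization, spot filters and the direction of the ratio are also not given in the sources used here. Positive was read as higher at 36 °C, which is likely from the values because 20 of 24 measured heat shock genes were positive on all 4 arrays. The label field gives Cy5 for channel 1 while the label protocol names Cy3, and no dye swap is named, so a dye effect common to the arrays stays in each strain's response and cancels in the difference between the strains. The precision is limited by the number of arrays.

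The value table has 5188 spots in as many lines, of which 4933 carry 1 gene, 1 carries several and 254 carry none. Gene names came from the array's annotation and from the RefSeq table of assembly ASM294v3, used for names and neighbours only; 4930 of the 4933 lines with 1 gene matched it by gene ID and 3 kept the annotation's symbol. Spots without a value numbered 5 and 67 on the wild-type arrays and 4 and 56 on the mmi1-ts3 arrays, replicates 1 and 2 in that order. Values of the same gene were averaged. Of 4880 genes named, the 4771 with a value on all 4 arrays were tested and 109 were not. Each array was centred on its median over the tested genes; the medians subtracted were −0.10 and 0.07 (log2) on the wild-type arrays and −0.00 and 0.10 on the mmi1-ts3 arrays. The 25 °C levels of the strains were never on the same array, so only responses to the shift can be compared.

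Genes were tested with limma 3.58.1 in R 4.3.3. A model with a mean for each strain was fitted to all 4 arrays, with moderated variances (eBayes) and 1 spread estimate for both strains. The mean ratio of each strain was tested against 0, and mmi1-ts3 minus wild type was tested as the difference of the responses, all with Benjamini-Hochberg adjusted p under 0.05. The residual degrees of freedom were 2 and the prior degrees of freedom 3.56. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so none is given. Conditions were repeated according to the series record, but nothing states that the replicates came from separate cultures, so the p-values may measure technical spread alone.

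Lists of genes, 23 in all, were fixed before the data were examined, and the 22 with at least 4 measured members were tested with camera from limma, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. The list of Mmi1 targets draws partly on the study of these samples and is not independent evidence. Some lists were made by name patterns, and at least 10 members are known to be of another class: the histidine kinases mak1, mak2 and mak3, imp1, imp2 and dim1 under ribosome biogenesis, the RNase P genes rpp1, rpp21 and rpp40 under ribosomal proteins, and the kinase ssp1 under heat shock proteins. Counts include them; these lists were also tested without them, chosen after the data were seen. The rule for the named genes was also fixed before the data were examined. It takes, for the strain difference, up to 15 genes higher and 10 lower past the test and with separated arrays, filled to 10 and 5 with the largest separated differences where fewer pass. For each strain's response it takes the 8 highest and 8 lowest past the test with the same sign on both arrays. It adds mmi1, the measured Mmi1 targets, and 2 to 4 members of every other list, those with the largest absolute values in the comparison. Genes called separated have both mmi1-ts3 arrays beyond both wild-type arrays on the same side.

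The 25 alternative settings covered the centring and scaling of the arrays, the genes kept, the variance model, the thresholds, each array left out in turn, the array set as a block, the reading of the log base, and camera with an estimated correlation or the self-contained test fry in place of the preset. Camera with an estimated correlation rests on the 2 residual degrees of freedom and had little power here. A list that fails it is therefore not shown to owe its preset result to correlation. Of these, 10 were added, or used for a further result, after the data were seen, among them centring within print blocks and leaving out the last print block. Print blocks were taken as runs of 324 spots, the usual spacing of the repeated cdc2 control. Steps before and after the test were run in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

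The test was tried on simulated data of 4771 genes in the same design, 5 runs each. For the strain difference with 20 changed genes, 0% were recovered at a log2 difference of 1, 8% at 2, 52% at 3 and 88% at 4. With 200 changed genes, 4.4%, 71.2%, 93.2% and 98% were recovered at the same sizes. For the wild-type response with 20 changed genes, 0%, 64%, 92% and 96% were recovered. For the strain difference with 20 changed genes and the array set as a block, 0%, 0%, 4% and 20% were recovered. Simulated genes were independent and the simulated array sets did not differ. The block figures therefore show only the cost of a lost degree of freedom, not what a block does in these data. The wild-type figures assume far fewer changed genes than the 1336 called in that response.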

Results

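The response of fission yeast to 30 min at 36 °C was measured as the ratio to the same strain at 25 °C, on 2 arrays of the wild type and 2 of mmi1-ts3. Mmi1 is an RNA-binding protein that marks meiotic transcripts for destruction during vegetative growth, and the mutant allele was shifted to its restrictive temperature. The question named by the series record is which transcripts differ with and without Mmi1 function. Values were present for 5183 and 5121 spots on wild-type replicates 1 and 2 and for 5184 and 5132 spots on mmi1-ts3 replicates 1 and 2. Errors given as SD are between the 2 arrays of a strain; those of a difference are the SE of the fitted model, with n = 2 per strain. The log base rests on the range of the values, as described with the processing. For a strain difference, higher or lower in mmi1-ts3 refers to the response to the shift, not to the transcript level.

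Of the 10 separated genes with the largest positive differences between mmi1-ts3 and the wild type, 5 are on the list of Mmi1 targets, which was partly chosen on these samples, and 4 on that of recombination, pairing and cohesion, with rec8 on both. In mmi1-ts3, mug9 was 7.23-fold above its wild-type response (log2 2.85 ± 0.29 SE), crs1, a meiotic cyclin, 6.78-fold (2.76 ± 0.31), and mug8 4.98-fold (2.32 ± 0.25). Next came rec8, the meiotic cohesin subunit, at 4.66-fold (2.22 ± 0.30) and tht2, a gene of nuclear fusion, at 4.58-fold (2.19 ± 0.36). The differences of meu26 (2.10 ± 0.60), rec25 (1.83 ± 0.45), tms1 (1.73 ± 0.54), mug45 (1.70 ± 0.25) and bqt1 (1.60 ± 0.29), which ties telomeres to the spindle pole body in meiosis, came next. At the other end of the separated genes stood inv1, the invertase, at 0.295-fold (−1.76 ± 0.23), SPOM_SPCC594.04C (−1.50 ± 0.23), elc1 (−1.40 ± 0.41), atf31 (−1.38 ± 0.62) and exg1, a glucan glucosidase (−1.33 ± 0.42). None of these passed the test over all genes. With 1 array left out, meu26 ran from 1.27 to 2.94, tms1 from 0.95 to 2.52, elc1 from −1.91 to −0.89, atf31 from −2.10 to −0.66 and exg1 from −1.86 to −0.80.

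With limma, 0 genes were higher and 0 lower in mmi1-ts3 at an adjusted p under 0.05. The smallest adjusted p was 0.254, and 0.311 with the array set as a block. At an unadjusted p under 0.05, 49 genes were higher and 41 lower, which is 1.89% of those tested. That share is smaller than the 0.05 expected if no gene differed. The main fit has no term for the array set, so the difference between the sets adds to its spread. Without mmi1-ts3 replicate 2, mug9 (2.99, adjusted p = 0.0374) and crs1 (3.10, adjusted p = 0.0321) passed, and with centring within print blocks, chosen after the data were seen, mug9 passed (2.92, adjusted p = 0.0374).

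By size alone, 9 genes lay at least 2-fold higher on both mmi1-ts3 arrays than on both wild-type arrays and 2 at least 2-fold lower. At 3-fold the counts were 5 and 1. With any 1 array left out, which leaves fewer arrays to separate, 25 to 44 genes were 2-fold higher and 11 to 41 lower. Regardless of size, 447 genes (9.37%) were separated higher and 974 (20.4%) lower, against 16.7% in each direction for exchangeable arrays, a share that does not allow for the difference between the array sets. The median difference over all genes was −0.07, and −0.09 and −0.06 in the uncoded and coded sets. Without centring it was −0.00.

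Of the 16 measured Mmi1 targets, 15 had a positive difference and the list's median was 1.10, or 1.62 in the uncoded and 0.67 in the coded set. Besides mug9, crs1, mug8, rec8 and mug45, the differences were 1.31 ± 0.29 for jnm1, 1.17 ± 0.52 for num1, which anchors dynein at the cell cortex, 1.16 ± 0.25 for rec10, 1.04 ± 0.53 for ssm4, 1.01 ± 0.23 for spo5 and 0.78 ± 0.30 for mug10. They were 0.32 for mei4, the meiotic transcription factor, 0.22 for rem1, 0.10 for mug4 and −0.14 for mug5. With 1 array left out, num1 ran from 0.49 to 1.85, ssm4 from 0.41 to 1.67 and mei4 from 0.036 to 0.59. The difference of mcp7 was 0.70 ± 0.996, and its wild-type values of −0.18 and 3.05 lay far apart; the high one belongs to replicate 2, on which spots nearby in the table were also far above the other arrays. The transcript of mmi1 itself differed by 0.06 ± 0.46. The signs of mcp7, rem1, mug4, mug5 and mmi1 changed when single arrays were left out, to −0.91, −0.12, −0.10, 0.57 and −0.56 at most.

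**Figure D1:**
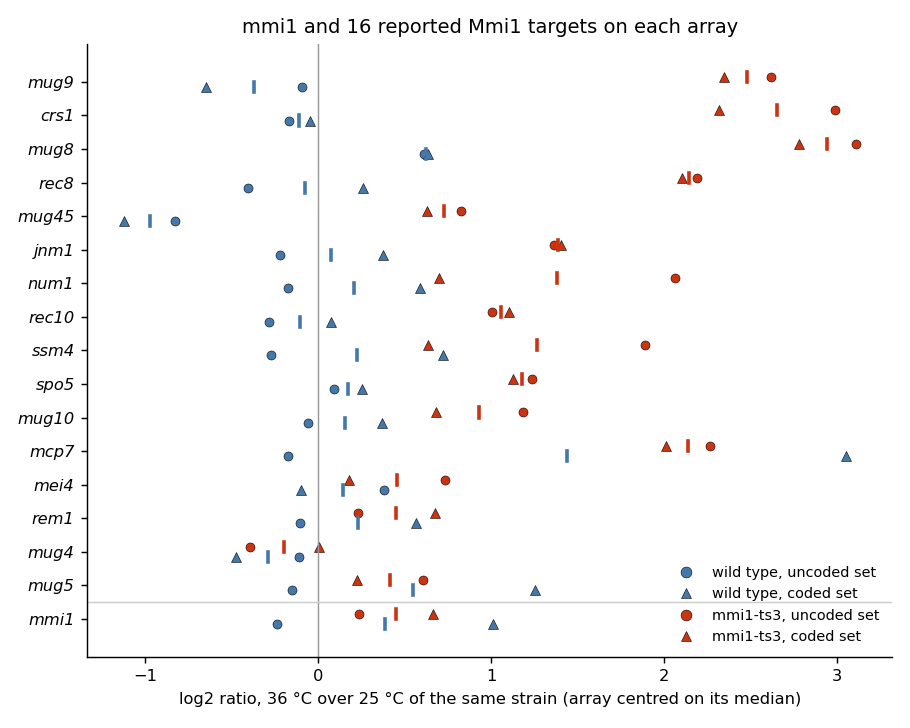
Log2 ratio of 36 °C over 25 °C on each array for mmi1 and the 16 measured Mmi1 targets, with circles for the uncoded set, triangles for the coded set and a bar for each strain's mean of 2 arrays. For mug9, crs1, mug8, rec8 and mug45 both mmi1-ts3 arrays lie above both wild-type arrays, and for mcp7 the coded wild-type array lies at 3.05.

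The list of Mmi1 targets was higher in mmi1-ts3 by camera (adjusted p = 7.27e-23), with 10 of 16 members separated higher. The adjusted p was 0.351 with an estimated correlation, and 0.31 by the directional test of fry; its test for change in either direction gave 0.035. Adjusted over the list alone, 8 members passed (mug9, mug8, crs1, rec8, mug45, rec10, jnm1 and spo5) against 0 over all genes. The list was partly chosen on these samples, so neither count is independent evidence.

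Genes of meiotic recombination, pairing and cohesion were also higher in mmi1-ts3, with a median of 0.71 over 28 members, 0.92 in the uncoded and 0.23 in the coded set (camera, adjusted p = 1.16e-15). The adjusted p was 0.351 with an estimated correlation. The list shares rec8, rec10, mcp7, num1 and ssm4 with the Mmi1 list, which was partly chosen on these samples. Its 23 members outside the Mmi1 list had a median of 0.45, or 0.53 and 0.236 in the uncoded and coded sets. Besides rec8, tht2, rec25 and bqt1, the members mek1, a meiotic checkpoint kinase (1.32), and rec27 (1.01) stood out; these last were named after their values were seen. Of the 28, 16 were separated higher and 0 lower, and 7 passed adjusted over the list alone (rec8, tht2, bqt1, mek1, rec10, rec25 and rec27), against 0 over all genes.

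The other meiotic lists had smaller medians over both sets; differences between lists were not tested. The 16 meu genes had a median of 0.35, or 0.58 and 0.36 in the uncoded and coded sets (camera, adjusted p = 3.14e-05). Their adjusted p was 0.373 with an estimated correlation. Among them, meu26 (2.10) and meu43 (1.21) were positive, while meu34 (−1.43 ± 1.85) had a single wild-type value of 5.27 on replicate 2. The 86 mug genes had a median of 0.10, or 0.11 and 0.01 in the sets (adjusted p = 0.000175, and adjusted p = 0.373 with an estimated correlation), and 3 passed adjusted over the list alone, mug9, mug8 and mug45, all of them also on the Mmi1 list. With 1 array left out the median of the mug genes ran from −0.07 to 0.23. Meiotic divisions and sporulation had a median of 0.14 over 23 members, with 0.34 and −0.08 in the sets (adjusted p = 0.00121, and adjusted p = 0.435 with an estimated correlation). Its adjusted p was 0.16 without the genes it shares with the Mmi1 list, and crs1 alone passed over the list. Entry into meiosis and mating had a median of 0.11 over 29 members (from −0.006 to 0.185 with 1 array left out), with 0.18 and 0.02 in the sets (adjusted p = 0.0186, and adjusted p = 0.373 with an estimated correlation). In it, the pheromone gene mfm1 (1.09 ± 0.53), the meiotic regulator mei2 (0.95 ± 0.40) and rep1 (0.60 ± 0.36) were highest; with 1 array left out they ran from 0.34 to 1.84, 0.43 to 1.47 and 0.15 to 1.04. Without wild-type replicate 1 the calls of the meu genes (0.807), mug genes (0.603), meiotic divisions (0.714) and entry into meiosis (0.343) were lost, the last also without wild-type replicate 2 (0.0572) and mmi1-ts3 replicate 1 (0.312).

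As a list, ribosomal protein transcripts fell more in mmi1-ts3 than in the wild type, with median responses of −0.96 and −0.65. The median difference over 126 members was −0.32, and −0.37 and −0.28 in the uncoded and coded sets. Of the members, 122 were below 0 and 91 separated lower. Examples were rpl3202 (−0.69 ± 0.24), rpl1102 (−0.58 ± 0.23) and rpl15 (−0.56 ± 0.24), and 0 members passed on their own. The list passed camera (adjusted p = 2.51e-14), with an adjusted p = 0.435 with an estimated correlation. The 11 measured Tf2 retrotransposons had a median of −0.50, or −0.37 and −0.52 in the sets, with all 11 below 0, such as Tf2-1 (−0.61, from −0.89 to −0.33 with 1 array left out) and Tf2-3 (−0.58, from −0.87 to −0.29). They passed camera (adjusted p = 3.14e-05, and adjusted p = 0.435 with an estimated correlation). Their estimated correlation was 0.575, the highest of the tested lists, against the preset 0.01. The 11 elements therefore cannot be taken as independent measures, and cross-hybridisation between them was not tested. They rose in both strains, by medians of 0.97 in the wild type and 0.46 in mmi1-ts3, so the difference is a smaller rise. Translation factors had a median of −0.24 over 35 members (adjusted p = 0.0252, and adjusted p = 0.373 with an estimated correlation), with tif308 at −0.46 (from −0.64 to −0.28 with 1 array left out), and lost the call whichever array was left out (adjusted p from 0.124 to 0.33).

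**Figure D2:**
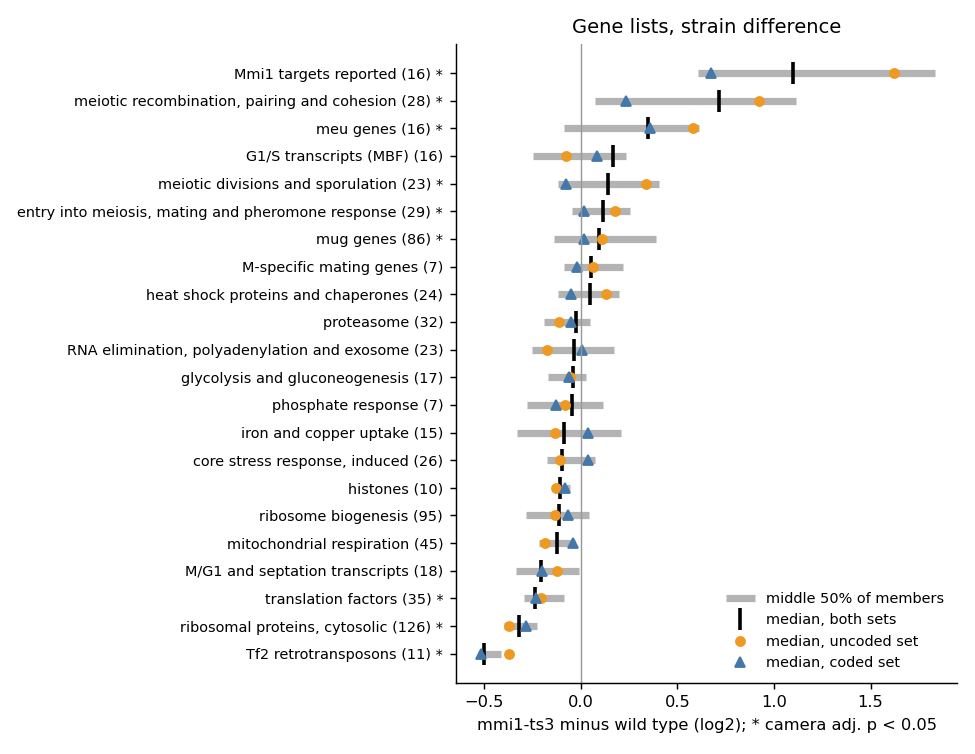
Median log2 difference, mmi1-ts3 minus wild type, of the 22 tested lists, with black bars for the median over both array sets, circles and triangles for the sets, grey bars for the middle 50% of members and the number of members in parentheses. Mmi1 targets lie highest with a median of 1.10 and Tf2 retrotransposons lowest with −0.50; an asterisk marks an adjusted p under 0.05 by camera.

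The remaining 13 tested lists did not pass, with medians from −0.21 to 0.17 and a smallest adjusted p of 0.142. Heat shock proteins differed by a median of 0.05 (adjusted p = 0.281), with hsp9 at −0.71 ± 0.36, sks2 at −0.54 ± 0.23 and hsp78 at 0.50 ± 0.31; with 1 array left out hsp9 ran from −1.15 to −0.27 and hsp78 from 0.26 to 0.74. Ribosome biogenesis had a median of −0.11 with dbp2, an RNA helicase, at 1.37 and ltv1 at −0.79 (from −1.09 to −0.50 with 1 array left out). Core stress genes had a median of −0.09, with zym1 at −0.92 (from −1.88 to 0.045 with 1 array left out), although camera placed the list on the upper side. Medians were −0.21 for M/G1 and septation genes, with slp1 at −0.98 (from −1.37 to −0.59 with 1 array left out), and −0.04 for RNA elimination and exosome genes, with mei2 at 0.95 and mtl1 at −0.77. They were 0.17 for G1/S genes, −0.11 for histones, −0.08 for iron and copper uptake, 0.06 for M-specific mating genes and −0.12 for mitochondrial respiration. With 1 array left out each of these medians took both signs, such as −0.18 to 0.21 for G1/S genes and −0.20 to 0.05 for histones. They were −0.05 for phosphate response, −0.04 for glycolysis and −0.02 for the proteasome. The P-specific mating genes had 2 measured members with a median of 0.20 and were not tested.

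In the wild type, the shift to 36 °C raised heat shock and stress transcripts and lowered those of ribosome production. The small heat shock proteins hsp16 (167-fold, log2 7.38 ± 0.50 SD) and hsp9 (80.6-fold, 6.33 ± 0.62) rose most, followed by rtc3 (6.22), ddr48 (5.98), lsd90 (5.48 ± 2.92, with single arrays at 7.55 and 3.42), rds1 (5.35), tsp0 (5.33) and SPOM_SPAC637.03 (5.19). The largest falls were those of SPOM_SPAC8E11.10 (−3.64), dbp3 (−3.49) and dbp2 (−3.30), RNA helicases of ribosome assembly, adg1 (−3.19), ani1 (−3.13), SPOM_SPBC887.17 (−3.02), the glutamine synthetase gln1 (−3.01) and the iron transporter str1 (−2.97). By limma, 643 genes were higher and 693 lower than at 25 °C, of which 387 and 396 by at least 2-fold. The counts were 416 and 434 without wild-type replicate 1, and 353 and 296 without replicate 2.

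Of 24 heat shock genes, 18 rose and 1 fell, with a median of 1.26 and examples hsp78 (4.12) and hsp104 (4.04), both disaggregases (camera, adjusted p = 4e-09). Their adjusted p was 0.238 with an estimated correlation. The direction of the ratio was read from these same genes, so the direction of this list is not independent evidence. Of 26 core stress genes, 17 rose and 1 fell, with ctt1, the catalase, at 4.94 (median 2.07, adjusted p = 1.68e-09, and adjusted p = 0.149 with an estimated correlation). Of 32 proteasome genes 12 rose, among them rpt5 (1.13, adjusted p = 0.0581 without wild-type replicate 2) and rpt6 (0.92, adjusted p = 0.0912 and 0.15 without replicate 1 or 2), with a median of 0.58 (adjusted p = 2.55e-06, and adjusted p = 0.41 with an estimated correlation). Of 11 Tf2 elements 10 rose, with a median of 0.97 (adjusted p = 5.31e-05, and adjusted p = 0.41 with an estimated correlation). The estimated correlation of this list was 0.575, so its members cannot be taken as independent measures. The calls of its highest members were lost when a wild-type array was left out, with an adjusted p of 0.0865 for Tf2-2 (1.10) without replicate 1, 0.095 and 0.0638 for Tf2-1 (1.02) without replicate 1 or 2, and 0.0681 and 0.0914 for Tf2-3 (1.02). Mitochondrial respiration genes had a median of 0.32, 5 of 45 rising and 1 falling (adjusted p = 0.0231, adjusted p = 0.697 with an estimated correlation, 0.301 without wild-type replicate 1, and 0.0666 without either mmi1-ts3 array).

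Of 95 ribosome biogenesis genes 71 fell, with nop2 at −2.67 and a median of −1.39 (camera, adjusted p = 4.35e-23, and adjusted p = 0.108 with an estimated correlation). Of 126 ribosomal protein genes 65 fell and 1 rose, with a median of −0.65 (adjusted p = 2.6e-17, and adjusted p = 0.41 with an estimated correlation), such as rps2802 (−1.33), rpp202 (−1.09), rpp0 (−1.08) and rpl102 (−1.04). Of these calls, rps2802 (then −1.03) and rpp202 (−0.75) were lost without wild-type replicate 2 and rpp0 (−1.03) without replicate 1. The call of rpl102 was not tried with arrays left out. Of 35 translation factors 21 fell, led by tif11 (−1.63), with a median of −0.84 (adjusted p = 4e-09, and adjusted p = 0.149 with an estimated correlation). Of 18 M/G1 and septation genes 6 fell, among them eng1, the septum glucanase (−2.26), and adg3 (−2.26), with a median of −0.53 (adjusted p = 0.00435, and adjusted p = 0.41 with an estimated correlation). The other 13 lists tested did not pass (smallest adjusted p 0.0543). With the array set as a block, RNA elimination (−0.37) and G1/S genes (−0.40) passed as lower, both with an adjusted p of 0.0426. Both had 0.41 with an estimated correlation and no block. RNA elimination also passed without centring (0.0417), and the mug genes (median 0.17, adjusted p = 0.0698) passed as higher without wild-type replicate 1 (0.30, adjusted p = 0.00767). Among the 13, the Mmi1 targets had a median of 0.15 (adjusted p = 0.84), with −0.16 on wild-type replicate 1 and 0.31 on replicate 2. The medians of the 13 ran from −0.40 to 0.17.

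In mmi1-ts3, heat shock and stress transcripts were again among those that rose most, and 4 meiotic lists passed camera with the preset correlation, but 0 with an estimated one. The gene lsd90 (157-fold, 7.30 ± 0.14 SD) and hsp16 (148-fold, 7.21 ± 0.57) rose most, then ddr48 (6.64), rtc3 (5.75), hsp9 (5.62), ctt1 (5.42), SPOM_SPAC637.03 (5.30) and rds1 (5.18). The largest falls were those of SPOM_SPAC8E11.10 (−3.87), adg1 (−3.66), str1 (−3.36), dbp3 (−3.29), ani1 (−3.28), nop2 (−3.27), apt1 (−3.27) and grn1 (−3.18). By limma, 711 genes were higher and 933 lower than at 25 °C, of which 426 and 562 by at least 2-fold. The counts were 367 and 535 without mmi1-ts3 replicate 1, and 462 and 514 without replicate 2.

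Of the 16 Mmi1 targets, 11 rose and 0 fell in mmi1-ts3, led by mug8 (2.94), crs1 (2.65), mug9 (2.48) and rec8 (2.15), with a median of 1.22 (camera, adjusted p = 1.13e-05). The adjusted p was 0.305 with an estimated correlation and 0.0256 by the directional test of fry, and the list is in part chosen on these samples. Adjusted over the list alone, 12 passed. Recombination genes had a median of 0.76, 12 of 28 rising and 1 falling (adjusted p = 0.00197, adjusted p = 0.349 with an estimated correlation, and 0.0256 by the directional test of fry). Of 86 mug genes 20 rose and 4 fell, with mug147 at 4.01 and a median of 0.35 (adjusted p = 0.000703, adjusted p = 0.27 with an estimated correlation, and 0.0359 by the directional test of fry). Part of this was shared with the wild type, where 13 mug genes rose and 2 fell. There mug147 rose by 3.80, and ste11 of the entry list by 0.96. Genes of entry into meiosis had a median of 0.40 and 1 of 29 rose, ste11, the regulator of mating genes (1.08); their adjusted p of 0.0165 became 0.0719 without mmi1-ts3 replicate 1, with adjusted p = 0.27 with an estimated correlation.

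Of 24 heat shock genes, 20 rose and 1 fell in mmi1-ts3, with hsp78 at 4.62, hsp104 at 4.25 and a median of 1.36 (camera, adjusted p = 2.74e-09, and adjusted p = 0.233 with an estimated correlation). As in the wild type, their direction is not independent evidence, because the direction of the ratio was read from them. Of 26 core stress genes 18 rose and 2 fell, with a median of 2.17 (adjusted p = 2.74e-09, and adjusted p = 0.146 with an estimated correlation). Of 32 proteasome genes 11 rose, with rpt5 at 1.17, rpn11 at 1.07 (adjusted p = 0.062 without mmi1-ts3 replicate 2) and a median of 0.52 (adjusted p = 2.48e-05, and adjusted p = 0.491 with an estimated correlation). Of 126 ribosomal protein genes 114 fell and 1 rose, with a median of −0.96 (adjusted p = 1.34e-21, and adjusted p = 0.27 with an estimated correlation). Of 95 ribosome biogenesis genes 73 fell, with a median of −1.61 (adjusted p = 4.25e-20, and adjusted p = 0.126 with an estimated correlation). Of 35 translation factors 26 fell, with a median of −0.94 (adjusted p = 2.74e-09, and adjusted p = 0.146 with an estimated correlation). Of 18 M/G1 genes 10 fell and 1 rose, with a median of −0.70 (adjusted p = 0.00275, and adjusted p = 0.27 with an estimated correlation).

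Histones had a median of −0.39 in mmi1-ts3, 2 of 10 falling (adjusted p = 0.0346, and adjusted p = 0.523 with an estimated correlation). That adjusted p was 0.142 without mmi1-ts3 replicate 1 and 0.155 without replicate 2, 0.0547 with centring within print blocks and 0.0521 without the last print block. Tf2 elements had a median of 0.46 with 0 members past the test (adjusted p = 0.00827, and adjusted p = 0.523 with an estimated correlation), and 0.142 without mmi1-ts3 replicate 1. With an estimated correlation of 0.575, the elements cannot be taken as independent measures here either. The highest member, Tf2-2 (0.66, adjusted p = 0.0607), passed with the array set as a block (0.02), without centring (0.0345) and with only that strain's arrays in the fit (0.0448). The other 9 lists did not pass (smallest adjusted p 0.0766), with medians from −0.20 to 0.47. Among them, meiotic divisions (0.40) and the meu genes (0.47, adjusted p = 0.0913) passed as higher when either wild-type array was left out (0.0477 and 0.0464), and meiotic divisions also with the array set as a block (0.0464).

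Across genes, which are not independent replicates, the mean responses of the strains correlated with r = 0.941 and rho = 0.911. Genes called higher in both strains numbered 511 and lower in both 635, against 95.8 and 136 for independent lists. The 1 gene called in opposite directions was mug45, at −0.97 in the wild type (adjusted p = 0.0143) and 0.73 in mmi1-ts3 (adjusted p = 0.0274). The strain differences of the array sets correlated across genes with r = 0.002 and rho = 0.032. Single arrays correlated at 0.907 between the strains in the uncoded set and 0.873 in the coded set, against 0.774 between the wild-type arrays and 0.868 between the mmi1-ts3 arrays.

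**Figure D3:**
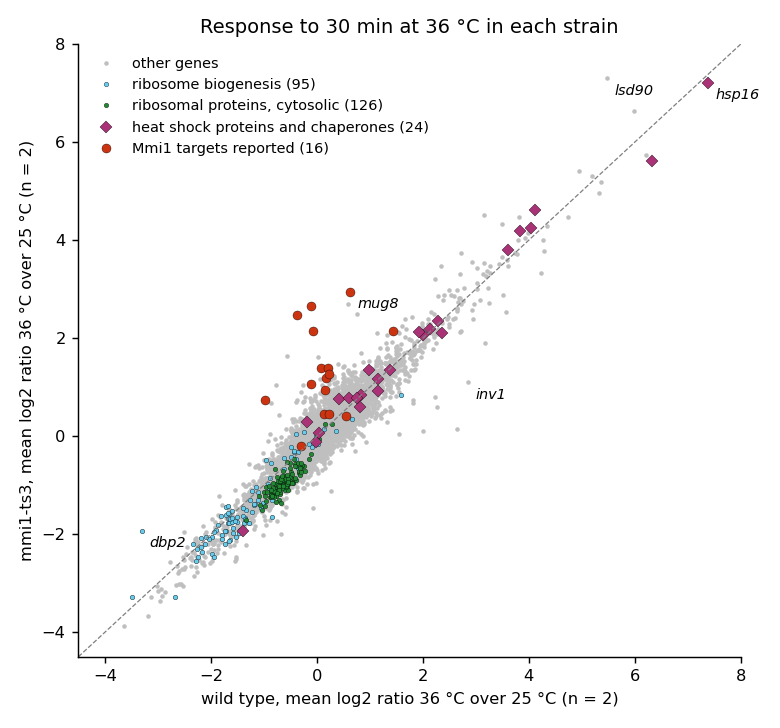
Mean log2 ratio of 36 °C over 25 °C of each of the 4771 tested genes, wild type on the x axis and mmi1-ts3 on the y axis (n = 2 arrays each), with the dashed line at equal response. Heat shock genes lie near the line with hsp16 at 7.38 and 7.21, while Mmi1 targets such as mug8 lie above it.

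**Figure D4:**
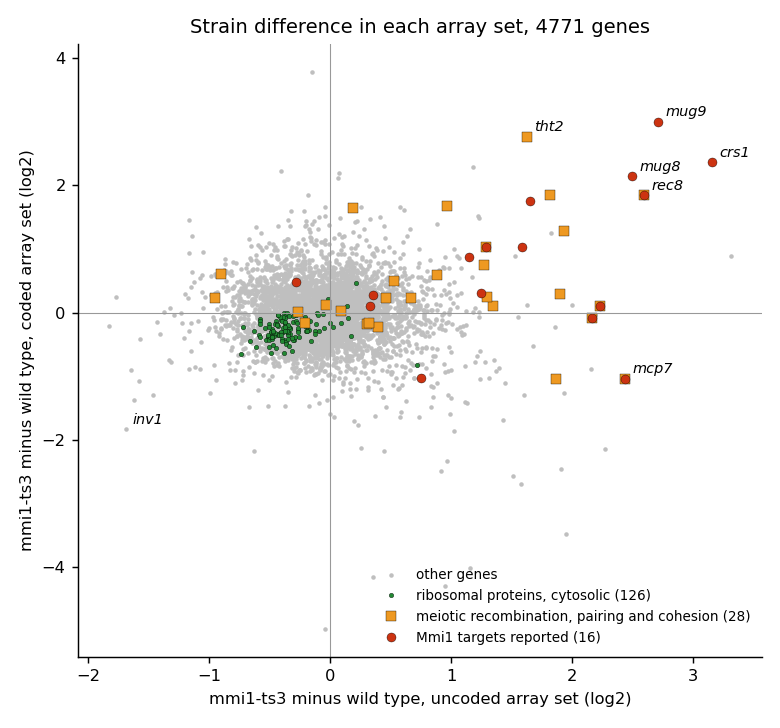
Log2 difference, mmi1-ts3 minus wild type, of the 4771 tested genes in the uncoded set (x axis) and in the coded set (y axis), 1 array per strain in each. Over all genes the sets correlate with r = 0.002, while mug9, crs1, mug8, rec8 and tht2 lie high and inv1 low in both.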

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

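The tests chosen only after the result was seen are those of the array sets and the 25 °C level for the Mmi1 targets and of the recombination genes, of single-spot noise for the array sets, and of wider ratios and bright spots for the ribosomal proteins; which tests are given, how some were read, and leaving members of another class out of the ribosomal tests were also decided after values were seen.

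For 10 named genes, both wild-type arrays lay below 0 and both mmi1-ts3 arrays above 0, with differences of 2.85 for mug9, 2.76 for crs1, 2.19 for tht2, 1.83 for rec25, 1.70 for mug45, 1.54 for the long non-coding RNA nc-pho1, 1.32 for mek1, 1.21 for meu43, 0.95 for mei2 and 0.58 for meu10. This difference in direction was not tested, and none of the 10 differences passed limma's test over all genes. Of all tested genes, 44 showed this order of signs and 69 the opposite one. The names nc-pho1 and mek1 were chosen after their values were seen.

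By camera, the lists differed between the strains with medians of 1.10 for Mmi1 targets, 0.71 for recombination, 0.35 for meu genes, 0.14 for meiotic divisions, 0.11 for entry into meiosis and 0.10 for mug genes. They lay at −0.24 for translation factors, −0.32 for ribosomal proteins and −0.50 for Tf2 elements. With an estimated correlation the smallest adjusted p of any list was 0.351. Among the 243 spots with 4 values and no single gene, 1 lay at least 2-fold higher on both mmi1-ts3 arrays and 0 lower. That spot is assigned to several genes, one of them a gene fixed in the Mmi1 list and not measured alone, and had values of −0.01 and 0.60 in the wild type and 2.37 and 2.44 in mmi1-ts3, a difference of 2.11.

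Reported Mmi1 targets were higher in mmi1-ts3 than in the wild type, with a median difference of 1.10. A difference between the array sets (medians of 1.62 and 0.67 within them) and noise of spots that vary much between arrays (0 of 10000 matched random lists as high) stay open for this list, because it was partly chosen on these arrays. The 23 recombination genes outside it had a median of 0.45. Their medians within the sets, 0.53 and 0.236, lay above the upper bounds of random lists, 0.085 and 0.14, and 0 of 10000 matched lists were as high. For genes that vary independently, these values argue against both. Such lists leave out spread between arrays, and each set holds 1 array per strain. The estimated correlation of the whole recombination list was 0.0726, so a shift that these genes share on single arrays stays open. A lower level of these transcripts in mmi1-ts3 at 25 °C cannot be told apart from a stronger response, because 0 arrays set one strain against the other. Loss of Mmi1 function may account for the difference, as a hypothesis, and the strain background, confounded with the allele, was not tested.

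The array sets differed across genes more than the strains did, with an SD of 0.476 for coded minus uncoded against 0.323 for mmi1-ts3 minus wild type. Noise of single spots as the only source is argued against, because the set differences of the strains correlated across genes with r = 0.379. At that size of r much of the set difference is not shared by the strains, so such noise stays open as a partial source. The position in the print blocks explained 28.1% of the variance of the set difference and 9.31% of that of the strain difference, and stays open as a partial source. As the whole of what the strains share it is argued against, since r was 0.371 before and 0.348 after block medians were subtracted. No biological explanation was tested, as the labels give none.

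Ribosomal protein transcripts were lower in mmi1-ts3, with a median of −0.32 over 126 genes and −0.37 and −0.28 in the array sets. A wider range of ratios on the mmi1-ts3 arrays is argued against by the medians. Ribosome biogenesis genes, which fell more in both strains, differed by −0.148 over 89 genes without those of another class. A permutation test of genes against the ribosomal proteins gave p = 1e-05 (two-sided), the smallest it can give. That test treats genes as independent, although the estimated correlation of the ribosomal proteins was 0.197. Its p therefore does not measure spread between arrays. The slope of mmi1-ts3 on wild type across genes was 1.005 in the uncoded and 0.875 in the coded set. Cross-hybridisation between paralogs is argued against by the 20 genes named without a paralog, at −0.291 (bootstrap 95% interval over genes −0.388 to −0.256). Bootstrap intervals in this paragraph were drawn over genes, so they too leave out spread between arrays. A bias of bright spots stays open. The 17 genes of the glycolysis list had a median of −0.038 (−0.167 to 0.028), but spot intensities were not used, so they were not shown to be bright. A difference between the strains may account for it, as a hypothesis, but neither the allele nor the strain background was tested and other technical sources were not examined.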

How the results depend on the processing

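Settings chosen only after the data were seen are print-block centring, leaving out the last print block or list members of another class, the natural-log reading, tests of unnamed spots, the set block for each strain's response and for the lists, and the left-out arrays for the 2-fold counts and the correlation. Of 2214 results of named genes under other settings, 2170 kept direction and side of the threshold, 11 passed only there, 21 no longer passed and 12 reversed. For lists, 711 kept the side of the threshold, 13 passed only there and 65 no longer passed. The 711 include changes of direction in lists that passed neither time. With 1 array left out, the median strain difference ran from −0.22 to 0.12 for the proteasome and from −0.43 to 0.09 for iron and copper uptake. With a 2-fold minimum the counts were 387 and 396 in the wild type and 426 and 562 in mmi1-ts3. With 1 array left out they ran from 353 to 680 and 296 to 666 in the wild type, 367 to 819 and 514 to 974 in mmi1-ts3, and 0 to 2 higher for the strain difference. Genes 2-fold apart ran from 25 to 44 higher and 11 to 41 lower, since fewer arrays must be separated, and lists higher from 2 to 6. The lone array is assumed to vary like the other strain. With print-block centring, 1 gene was higher and 16 were 2-fold higher. At 1.5-fold, 25 and 16 genes were apart, at 3-fold 5 and 1, and with natural logs 21 and 7. With an estimated correlation 0 lists passed in any comparison (Mmi1 targets 0.351, and 0.305 in mmi1-ts3, heat shock 0.238 and 0.233). That loss is not due to correlation alone. Core stress and ribosome biogenesis, with estimates of −0.0129 and −0.00902 below the preset 0.01, had an adjusted p of 0.149 and 0.108 in the wild type. With the directional test of fry 0 passed for the difference (Mmi1 targets 0.31). It passed 7 lists in the wild type, 3 of them higher, and 10 in mmi1-ts3. The 10 included Mmi1 targets (0.0256), recombination (0.0256), mug genes (0.0359) and entry into meiosis (0.049). Its test for change in either direction passed for the difference of Mmi1 targets (0.035) and mug genes (0.0121). With 1 array left out, differences that changed sign ran from −0.56 to 0.69 for mmi1, −0.91 to 2.31 for mcp7, −0.12 to 0.56 for rem1, −0.10 to 0.29 for mug4, −0.84 to 0.57 for mug5, −4.46 to 1.61 for meu34 and −1.88 to 0.045 for zym1; the reversed values not among these ends were −0.15 for mmi1, −0.086 for mug4, 0.054 for mug5 and −0.002 for rem1, and mmi1 stood at −0.052 with print-block centring; the cause was not tested. The array set as a block, which coincides with the replicate numbers, gave 0 and 0 genes for the difference, 928 and 919 in the wild type and 1011 and 1158 in mmi1-ts3, and changed no other named call than Tf2-2 in mmi1-ts3 and 3 list calls. Without list members of another class the medians of the strain difference were −0.15 for ribosome biogenesis, −0.32 for ribosomal proteins and 0.033 for heat shock proteins, and 70 of 89, 64 of 123 and 18 of 23 members fell or, for heat shock, rose in the wild type. Signal over background is not given in the sources used here, so its limits could not be assessed.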

Other observations

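The tests of the hexose transporters and of wild-type replicate 2 were chosen only after the result was seen, and that of the neighbouring genes before.

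The hexose transporter genes went both ways, with ght5 at −0.86 ± 0.25 (SE, n = 2 per strain), ght8 at −0.71 and ght6 at −0.65 but ght4 at 0.41 and ght3 at 0.35, the last higher in both array sets, and none past the test. The 8 measured family members had a median difference of −0.37, and 4 of them were lower in both array sets, as were 35.8% of all genes. A family-wide shift may be weighed with 35 of 10000 random lists of 8 genes reaching so low a median, but the family was picked for its lowest members, so the test leaves it open. Among single genes named after their values were seen, gal1, the galactokinase, differed by −1.08 and urg2 by −1.05.

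Transcripts running on from Mmi1 targets into the next gene could raise that gene. The 6 measured downstream neighbours on the same strand had a median difference of 0.02, and 2435 of 10000 random lists of that size were as high. The bound set beforehand for the opposite outcome was a poor one, because 6 genes are too few for a miss to exclude anything, so this stays open.

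On wild-type replicate 2, 24 spots lay at least 4-fold above the median of the other arrays, and 20 of them, 83.3%, were in the last print block, which holds 6.32% of the spots. On the other arrays the share of such spots in that block was 0% of 1 on wild-type replicate 1, 0% of 7 on mmi1-ts3 replicate 1 and 37.5% of 8 on mmi1-ts3 replicate 2. The block also held 7 of the 14 spots at least 4-fold below the others on wild-type replicate 1 and 6 of 7 on mmi1-ts3 replicate 1, so it stands apart on other arrays too. Whether replicate 2 has a fault in part of that array, a hypothesis found on the same values, stays open. The spots include meu34 and utp14, and mcp7 lies in the block. Without the block, the wild-type counts were 728 higher and 755 lower, those of mmi1-ts3 783 and 969, and the Mmi1 targets had a median difference of 1.16.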
